A study of Solanum lycopersicum with 4 samples.

How the data were processed

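RNA-seq was used to measure transcript levels in the first pair of true leaves of tomato (Solanum lycopersicum), cultivar Moneymaker, at 0, 3, 24 and 48 h after a shift to 10 °C. Per the labels' protocols, seedlings were raised at 25 °C under 100 µmol m-2 s-1 of light, and the cold treatment was given under 40 µmol m-2 s-1, both with 12 h of light per day. RNA was extracted with TRIzol, treated with DNase and purified on columns, and libraries followed standard Illumina protocols, per the labels' protocols. The 4 libraries were grouped by the time in their titles, which left 1 library per time. Whether a library came from 1 plant or from several pooled plants, and the hour of harvest, are not given in the sources used here.

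The deposited files held, for each gene, a count of unique reads, the gene length, the percent of the gene covered by reads, and an RPKM value, per the file headers. The aligner, counting tool, strand setting, genome build, annotation release and filters are not given in the sources used here. The deposited counts were whole numbers of at least 1, and their sum in each library equalled the total stated in its file header. Genes with no read were left off each deposited list. The authors' RPKM (reads per kilobase of gene length and per 1000000 unique reads) followed from the count, the length and that total, so it scaled every library by its plain total only. The coverage percent, per the file headers, was used only in a check for reads shared between neighbouring genes. If unique means that reads matching several copies were left out, these counts understate genes with near-identical copies.

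Ratios were computed from the deposited counts. Libraries were scaled with TMM factors (edgeR 4.0.16, R 4.3.3), which were 0.94 at 0 h, 0.90 at 3 h, 1.06 at 24 h and 1.12 at 48 h, and counts were expressed as CPM (counts per 1000000 reads of the scaled library). Ratios were taken as differences of log2(CPM + pseudocount), with a pseudocount equal to 5 reads at the mean library size (0.135 CPM), which understates the change of low genes. Genes were kept if they were listed in all 4 files and had a mean of at least 5 CPM over the 4 libraries. This left 13840 of the 26219 genes listed in any file, of which 22488 were listed in all 4. A gene was counted as different when its ratio was at least 4-fold. The edgeR package was used for scaling only. With 1 library per time the spread between plants cannot be estimated, so no p-value, standard error or replicate check exists for any difference, and each comparison is between these libraries.

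In units of 1000000 reads (M), the libraries held 38.5 M at 0 h, 36.1 M at 3 h, 35.7 M at 24 h and 37.4 M at 48 h. For single genes, fold values are ratios of scaled counts without the pseudocount, with exact Clopper-Pearson intervals (95%), while their log2 ratios include the pseudocount. At the filter limit of 5 CPM, about 185 reads per library, equal counts had an interval of -0.30 to 0.30 in log2. A count of 0 allows up to 3 reads. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Correlations of ratios that share the 0 h library were set beside 100 simulations of unchanged libraries with counting noise, which hold no plant-to-plant variation, and overlaps of calls beside the overlap of independent lists. On simulated data for the 3 h against 0 h comparison, in which 200 genes were changed and 13829 genes passed the filter, all 98 genes changed 8-fold that passed the filter were called, none of the 96 changed 3-fold and none of the 13635 unchanged genes were called. These simulated data also held counting noise only, with no plant-to-plant variation. They check the computation and give no rate of false calls between plants.

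Gene names for the identifiers were not found in the sources used here. The files give no names, and none of the 41476 genes in the RefSeq gene table of assembly SLM_r2.1 carried such an identifier. The 40 functional gene lists and the choice of named genes by function, both fixed before the data were examined, were therefore not used. The fallback rule fixed beforehand allowed at most 2 identifiers higher and 2 lower. They were the gene with the largest and the gene with the smallest ratio to 0 h at 3 h, and likewise at 48 h, a choice within that rule made before any ratio was computed. Time classes, thresholds and filters were also fixed before the data were examined, except the class of genes different at 24 h alone. That class and the groups by abundance, chromosome and neighbourhood were chosen after seeing the files. Chromosomes and gene order were read from the identifiers, which by convention number tomato genes along each chromosome. No genome coordinates were used.

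Alternatives were DESeq2 1.42.0 size factors, plain library totals, pseudocounts of 0.5 and 25 reads, no filter on low counts, a filter at 20 CPM, a 2-fold threshold, and genes absent from a file taken as 0. Other computations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and SciPy 1.17.1.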

Results

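The transcriptome of tomato leaves was profiled during the first 48 h at 10 °C, a temperature below the optimum for this chilling-sensitive crop, to describe how transcript levels shift while plants are exposed to the cold. The first pair of true leaves of 3-week-old Moneymaker seedlings was sampled at 0, 3, 24 and 48 h, with 1 RNA-seq library per time. The light level was lower during the cold treatment than during growth at 25 °C, so if the 0 h leaves were taken before the shift, as their time implies, the ratios to 0 h compare leaves that differed in both. The title of the 0 h library names 10 °C, as the titles of the other times do. The labels do not otherwise state the conditions at the 0 h harvest. The libraries held from 35.7 M (24 h) to 38.5 M (0 h) unique reads. Between 24049 (3 h) and 24472 (48 h) genes had at least 1 unique read in a library, and the median listed gene had from 241 (3 h) to 292 (48 h) reads. None of the values below has a replicate, so differences are described by size and by their counting error.

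The library at 3 h differed from that at 0 h, those at 24 and 48 h differed from it more broadly, and these later libraries differed little from each other. Nothing was sampled between 3 and 24 h, so separate steps cannot be told from a gradual course. Over the 13840 genes compared, log2 levels at 24 and 48 h were the most alike of any pair of libraries, with a Pearson correlation across genes of 0.97 (Spearman 0.97). The 0 and 3 h libraries followed with 0.95 (Spearman 0.94), and the 4 pairs that joined an earlier with a later library lay between 0.86 and 0.87 (Spearman 0.85 in each). These correlations are across genes, which are not independent replicates. The root mean square difference in log2 was 0.56 between 3 and 0 h, 0.86 between 24 and 0 h and 0.40 between 48 and 24 h. Within 2-fold of their 0 h level at all 3 later times were 10179 of the 13840 genes.

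After 3 h at 10 °C, 197 genes were at least 4-fold higher than at 0 h and only 8 were at least 4-fold lower. At the 2-fold level the numbers were 659 higher and 156 lower. The gene with the largest ratio was Solyc11g071740.1.1 on chromosome 11, with 9 reads (0.25 CPM) at 0 h and 2911 reads (89.9 CPM) at 3 h, a ratio of 361-fold (95% interval 190 to 790) without a pseudocount and a log2 ratio of 7.87 with it. Folds and intervals of single genes below are likewise without the pseudocount. Its transcript had 29 reads at 24 h, 3.06-fold the 0 h level (1.41 to 7.36), and 20 reads at 48 h, 1.92-fold the 0 h level with an interval of 0.84 to 4.80 that included no difference. The gene with the smallest ratio was Solyc08g080540.2.1 on chromosome 8, which went from 77 reads at 0 h to 4 reads at 3 h, 17.3-fold lower (6.47 to 64.9). Its log2 ratio was -3.13 with the pseudocount of 5 reads and -1.81, short of 4-fold, with 25 reads. With 25 reads it no longer had the smallest ratio, since 4 genes were still at least 4-fold lower. All 205 genes counted as 4-fold different had counting intervals that excluded a ratio under 2-fold. The 4-fold threshold with the pseudocount of 5 reads all but ensures this, so it adds no support for the calls. The share of higher genes among these 205 was 96.1%.

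Most of the genes that were higher at 3 h were nearer to their starting level on the following days. Of the 197, 111 lay within 2-fold of 0 h at 24 h and 107 at 48 h, and 90 did so at both times. Another 36 were still at least 4-fold higher at 24 h and 37 at 48 h, while 11 and 14 were at least 2-fold lower than at 0 h. The median log2 ratio of the 197 genes was 0.60 at 24 h and 0.70 at 48 h. The 90 genes that differed at 3 h alone had a median log2 ratio of 2.51 at 3 h, 0.08 at 24 h and 0.27 at 48 h. Only 2 genes followed the mirror course, lower at 3 h and back later. By selection the 197 genes are high at 3 h, so their early ratios are not independent evidence of size. Selection on a single library also favours smaller ratios at the other times. The 90 genes were in addition chosen to lie within 2-fold of 0 h later, so their later medians follow from that definition.

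**Figure D1:**
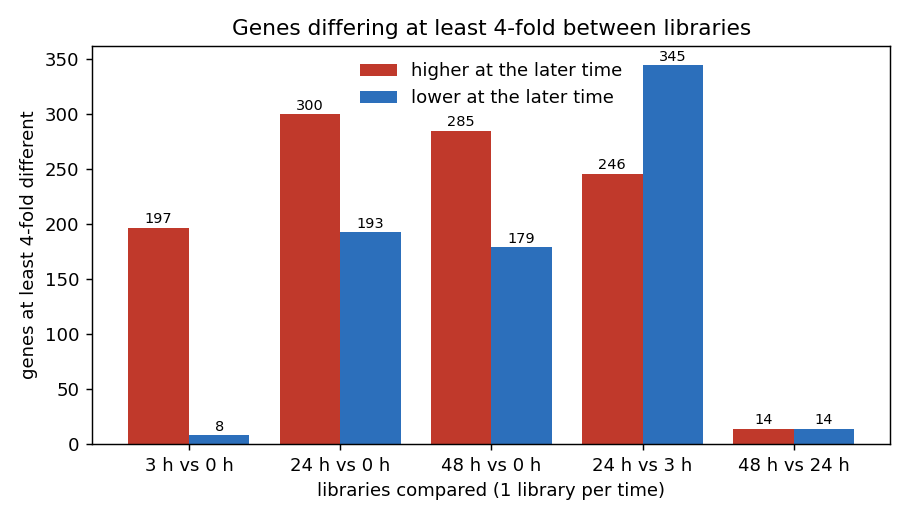
Number of genes at least 4-fold higher (red) or lower (blue) at the later of 2 times, for 5 comparisons of single libraries (y axis, genes). The 3 h against 0 h pair has 197 higher and 8 lower genes, and the 48 h against 24 h pair has 14 of each.

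By 24 h the change was broader and went in both directions. At least 4-fold higher than at 0 h were 300 genes, and 193 were at least 4-fold lower. At the 2-fold level 1335 genes were higher and 1146 lower, together 17.9% of the genes compared, against 5.89% at 3 h. Against 3 h, 246 genes were at least 4-fold higher at 24 h and 345 lower. By their times, the 3 and 24 h libraries also differed in the hour of day. All 4-fold differences at 24 h had counting intervals that excluded a ratio under 2-fold, which the threshold and pseudocount again all but ensure. The split between directions depended on the scaling. With plain library totals, as in the authors' RPKM, 383 genes were higher and 148 lower at 24 h than at 0 h, and 365 higher and 248 lower than at 3 h, since that scaling put the median log2 ratio of all genes at 0.20 against 0 h and at 0.25 against 3 h.

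At 48 h, 285 genes were at least 4-fold higher than at 0 h and 179 at least 4-fold lower. The largest ratio was that of Solyc03g117860.2.1 on chromosome 3, which had 16 reads (0.44 CPM) at 0 h, 55 at 3 h, 3969 at 24 h and 3666 (87.9 CPM) at 48 h, 198-fold above 0 h (122 to 348), with a log2 ratio of 7.25 once the pseudocount was added. Solyc10g008270.2.1 on chromosome 10 had the smallest ratio. It had 334 reads at 0 h, 621 at 3 h, 1 at 24 h and 8 at 48 h, where it was 48.2-fold lower than at 0 h (24.2 to 113), with a log2 ratio of -4.84 once the pseudocount was added. At 3 h the same gene was 2.07-fold higher than at 0 h (1.81 to 2.38). With plain library totals 427 genes were higher and 123 lower, with the median log2 ratio of all genes at 0.26.

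Between 24 and 48 h only 14 genes were at least 4-fold higher and 14 at least 4-fold lower, 0.20% of the genes compared. At the 2-fold level 155 were higher and 203 lower. Of the 300 genes higher at 24 h, 194 were still at least 4-fold higher at 48 h, 90 were 2- to 4-fold higher and 16 lay within 2-fold of 0 h. Of the 193 lower genes, 123 were still at least 4-fold lower, and all but 3 remained at least 2-fold lower. Independent lists of these lengths would share 6.18 higher and 2.50 lower genes. Both comparisons use the single 0 h library, which cannot be split, so part of the sharing may come from it.

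As defined here, the late groups held more genes than the sustained ones. Within 2-fold of 0 h at 3 h and at least 4-fold higher at both 24 and 48 h were 133 genes, with median log2 ratios of 0.06 at 3 h, 2.52 at 24 h and 2.57 at 48 h. The corresponding late and lower group held 103 genes, with medians of -0.37, -2.57 and -2.63. At least 4-fold higher at all 3 times were 27 genes, with medians of 2.61, 2.84 and 2.83, and 2 genes were lower at all 3 times. At least 4-fold from 0 h at 24 h and within 2-fold of it at both 3 and 48 h were 6 higher and 3 lower genes. The sizes and medians of these groups follow in part from how the groups were defined. Genes that were 2- to 4-fold from 0 h at 3 h fall in neither the late nor the sustained groups. Of the 300 genes higher at 24 h, 36 were at least 4-fold higher at 3 h and 65 were 2- to 4-fold higher. Another 193 lay within 2-fold of 0 h at 3 h and 6 were at least 2-fold lower. The ratios at 3 and 24 h, which share the 0 h library, had a correlation across genes of 0.29 and a covariance of 0.14, beside a covariance of 0.0034 from counting noise. The ratios at 24 and 48 h had a correlation of 0.89 and a covariance of 0.66, beside the same simulated covariance of 0.0034. Simulated correlations with no change were 0.49 and 0.53. In a pair of ratios with no library in common, 24 h to 0 h and 48 h to 3 h, the correlation was 0.67 and the covariance 0.52. In another pair with no library in common, 3 h to 0 h and 48 h to 24 h, the correlation was -0.09 and the covariance -0.019. The remaining such pair, 48 h to 0 h and 24 h to 3 h, was not computed.

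**Figure D2:**
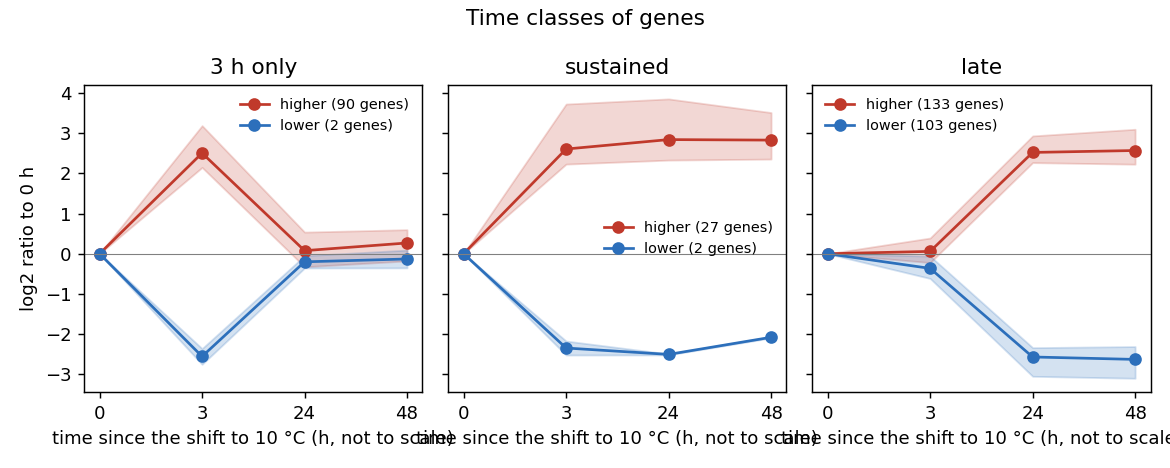
Log2 ratio to 0 h (y axis) against time since the shift to 10 °C (x axis, hours, not to scale) for genes different at 3 h only, at all times (sustained) or at 24 and 48 h but not at 3 h (late). Lines are medians over genes and bands the quartiles over genes, from 1 library per time. The courses follow in part from how the groups were defined. The largest groups are the late ones, with 133 higher and 103 lower genes.

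The 50 most abundant leaf transcripts were mostly lower after 24 and 48 h, while the wider set of abundant genes went both ways. The 50 genes with the highest mean level, a group chosen after seeing the data and each above 2121 CPM on average, took 27.5% of all reads at 0 h, 26.1% at 3 h, 18.8% at 24 h and 16.7% at 48 h. At 3 h 23 of them lay above and 27 below their 0 h level, with a median log2 ratio of -0.0059 and none beyond 2-fold. At 24 h 47 of the 50 were below 0 h, 21 of them at least 2-fold, with a median of -0.84 (quartiles -1.52 and -0.48). At 48 h 49 of the 50 were below, 28 at least 2-fold, with a median of -1.04 (quartiles -1.50 and -0.63). No gene of the 50 was 2-fold higher at any time. Among the 500 most abundant genes, 311 lay below and 189 above 0 h at 24 h, and 316 below and 184 above at 48 h, with medians of -0.20 and -0.26. Among the 2768 most abundant genes, with means above 61.8 CPM, the medians were 0.06 and 0.04, with 252 genes at least 2-fold higher and 210 lower at 24 h and 306 higher and 267 lower at 48 h. For the 50 genes, the median at 48 h was -0.79 with plain library totals and -1.02 with DESeq2 size factors.

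**Figure D3:**
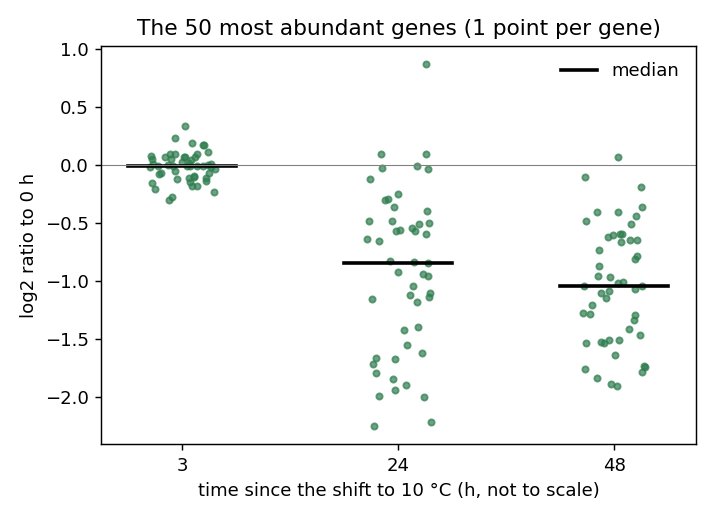
Log2 ratio to 0 h (y axis) of each of the 50 most abundant genes at 3, 24 and 48 h (x axis, hours since the shift to 10 °C, not to scale). Each point is a gene in 1 library and the bar is the median, which is -0.84 at 24 h and -1.04 at 48 h.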

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

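The tests of an hour-of-day effect and of the lower light were chosen only after the results were seen.

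Among the named genes, each chosen for an extreme ratio at 3 or 48 h, Solyc08g080540.2.1 and Solyc10g008270.2.1 were singled out. Their ratios to 0 h had opposite signs at 3 h and later, with counting intervals that excluded 0 on each side. This rule was applied to the named genes only, not to all genes compared. Over all genes compared, 24 were at least 2-fold higher at 3 h and 2-fold lower at both 24 and 48 h. Another 11 went the opposite way, 2-fold lower at 3 h and 2-fold higher at both later times. The log2 ratio of Solyc08g080540.2.1 was -3.13 at 3 h, 2.13 at 24 h and 2.07 at 48 h. That of Solyc10g008270.2.1 was 1.04 at 3 h, -5.86 at 24 h and -4.84 at 48 h. With 1 library per time, the difference between times was not tested against plant-to-plant variation.

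Genes without any read at 0 h, which no comparison used, carried reads later. Over 3 reads, the limit that a count of 0 allows, were seen for 101 such genes at 3 h, 172 at 24 h and 213 at 48 h. At least 50 reads were seen for 5, 3 and 6 of them, with a highest count of 516 at 3 h. In the other direction, 115 genes without a read at 3 h, 150 without one at 24 h and 114 without one at 48 h had over 3 reads at 0 h. At least 50 reads at 0 h were seen for 0, 2 and 1 of these, with highest counts of 21, 159 and 73. Without any read were 1994 genes at 0 h, 2170 at 3 h, 1986 at 24 h and 1747 at 48 h.

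The first pattern weighed is that 4-fold differences at 3 h were nearly all higher. The choice between the scalings used made little difference. With DESeq2 size factors or with plain totals, at least 94.3% of the genes called 4-fold different were higher. These scalings put the median log2 ratio of all genes at 0.0084 and -0.061. Shifts this small could hardly lower the share, so a scaling error common to all settings is not excluded. A gene length trend is argued against, since gene length and the ratio at 3 h had a Spearman correlation of only -0.02 across genes. The share was 95.6% among the genes called after subtraction of the median ratio of 20 length bins. Sampling at another hour of the day stays open. By their times, leaves at 24 and 48 h were due at the same hour as at 0 h, though the hour of harvest is not given. Genes following only the day would then be back by 24 and 48 h. Of the 197 higher genes, 45.7% lay within 2-fold of 0 h at both times, which short-lived responses to cold or to lower light could also give.

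The second pattern is the lower level of the 50 most abundant genes at 24 and 48 h. Neither the choice between the scalings used nor gene length accounts for it. The median log2 ratio at 48 h was at most -0.79 under other scalings and -1.09 after subtraction of the length bins. The other scalings put the median of all genes at 48 h at 0.030 and 0.26, so a larger scaling error common to all settings is not excluded. The median was nearer 0 for wider sets of abundant genes, at -0.52 for 200. Temperature and light cannot be told apart here, because per the protocols both were lowered for the treatment and no library from 25 °C under the lower light was analysed. The median at 3 h, when both were already lower, was -0.0059, which does not separate them. A response of abundant leaf transcripts to cold, to light or to both may underlie the pattern, as a hypothesis.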

How the results depend on the processing

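No paired analysis was possible because each time has 1 library, and no replicate could be left out for the same reason. Alternatives for the functional gene lists were not run, since the sources used here gave no names for the identifiers. DESeq2 size factors, plain library totals and a pseudocount of 0.5 reads kept all 10 counts of 4-fold different genes within 1.5 times. Even so, plain totals reversed which direction was larger at 24 h against 3 h, from 246 higher and 345 lower to 365 higher and 248 lower. They also raised the genes higher at 48 h than at 0 h from 285 to 427, close to that limit. Taking absent genes as 0 added no gene above 5 CPM, so that setting tests nothing. A pseudocount of 25 reads left 4 genes lower at 3 h than at 0 h and 9 lower at 48 h than at 24 h. Without a filter on low counts, over 22488 genes, there were 321 higher and 41 lower at 3 h, 522 and 386 at 24 h, and 545 and 337 at 48 h, each against 0 h, then 441 and 556 at 24 h against 3 h, and 72 and 32 at 48 h against 24 h. A minimum of 20 CPM, over 7490 genes, gave 112 and 2, 163 and 90, 134 and 86, 125 and 192, and 4 and 4, in the same order. The 2-fold threshold gave 659 and 156, 1335 and 1146, 1389 and 1173, 1140 and 1308, and 155 and 203, and the time classes then held 331 higher and 57 lower genes at 3 h only, 173 and 50 sustained, and 803 and 706 late. The filters compare more or fewer genes and the 2-fold threshold is a lower limit, which by construction moves these counts. With DESeq2 size factors 1 gene instead of 2 was lower at all 3 times, and the cause of this and of the pseudocount change was not tested. The 12 ratios of the 4 named genes kept their sign under the other scalings and pseudocounts. This tests little, since a change of pseudocount cannot turn a sign and the scalings moved these ratios little. With a pseudocount of 25 reads, Solyc08g080540.2.1 was no longer 4-fold different at any time, with log2 ratios of -1.81, 1.89 and 1.84 at 3, 24 and 48 h, and that of Solyc10g008270.2.1 at 24 h lay between -7.86 and -3.82 over these settings. With means of 5.35 and 7.16 CPM, these genes would be left out by the filter at 20 CPM. The alternatives for the most abundant genes were added after seeing the data. For the 200 most abundant genes the median log2 ratio was -0.39 at 24 h and -0.52 at 48 h, against -0.84 and -1.04 for 50. Equal counts of 185 reads, at 5 CPM, fix a ratio to within 1.23-fold, but a gene that passes the filter on its mean can have few reads in 1 library, such as Solyc10g008270.2.1 with 1 read at 24 h and an interval of 62.6- to 13913-fold. The spread between plants is unknown at any depth.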

Other observations

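The groupings by neighbourhood, chromosome and opposite course were chosen only after the files were seen, and so was the test without pairs of similar length. The other tests of explanations for neighbours were set before their results were seen. Genes that sit next to each other in the identifier order, which follows each chromosome, differed from 0 h in the same direction more often than shuffled genes. Among 7240 adjacent pairs, both genes were at least 2-fold higher in 39 pairs at 3 h, 119 at 24 h and 116 at 48 h, against means of 16.7, 68.1 and 73.9 when ratios were shuffled within chromosomes. Both were at least 2-fold lower in 81 pairs at 24 h and 92 at 48 h, against means of 49.0 and 51.3. None of 10000 shuffles reached any of these 5 counts. The counts are not separate results, since all ratios share the 0 h library and those at 24 and 48 h had a correlation of 0.89 across genes. At 3 h only 2 pairs were lower together, a count that 2182 of the shuffles reached. Pairs going opposite ways were not more frequent, with 91 at 24 h against a shuffled mean of 115. The correlation of neighbouring log2 ratios was 0.11 at 3 h, 0.12 at 24 h and 0.10 at 48 h. These counts describe the 4 libraries, and genes are not independent replicates. Pairs overlap where consecutive genes differ together, so a run of genes can count in several pairs. How far the excess came from a few such runs was not tested.

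Early and late responses went opposite ways in few genes. Of the 659 genes at least 2-fold higher at 3 h, 24 were at least 2-fold lower at both 24 and 48 h, where independent lists would give 37.1, and 173 were at least 2-fold higher at both, where independent lists would give 47.0. Of the 156 lower at 3 h, 11 were 2-fold higher at both later times, with 11.1 given by independent lists. All these ratios share the 0 h library, which favours the same sign. Only 3 genes were at least 2-fold different in opposite directions at 24 and 48 h. Among the 12 numbered chromosomes, the share of genes at least 4-fold different at 3 h was highest on chromosome 10 with 2.55% and lowest on chromosomes 9 and 11 with 0.80% each, while none of 76 genes with identifiers of chromosome 0 differed that much. Shuffled chromosome labels gave a share as high on some chromosome in 391 of 10000 draws at 3 h, before any allowance for looking at 3 times, and in 1905 and 2252 draws for the highest shares at 24 and 48 h.

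The third pattern weighed is this agreement of neighbours. Reads shared between near-identical copies stay open, because the coverage measure could not decide. Coverage of a gene was taken as its highest value over the 4 libraries. Among the 200 pairs that differed together at 24 h, the lower coverage of the 2 genes had a median of 95.5%, against 96.8% in the other 7040 pairs. The difference was -1.37 percentage points (95% bootstrap interval -2.23 to -0.15), above the -5 points set beforehand. It lay in the direction that shared reads would give. Both medians were close to full coverage, so the measure may miss shared reads in a part of the pairs. The bootstrap treated pairs as independent, although neighbouring pairs can share a gene. A gene length trend is argued against, since the neighbour correlation at 24 h was 0.13 after subtraction of the length bins. Tandem copies of similar length are argued against as the whole cause, since the neighbour correlation at 24 h was 0.11 over the 6284 pairs left without pairs of similar length, above the largest value of 0.053 in 10000 shuffles within chromosomes over the same pairs. Tandem copies in general stay open as a candidate explanation for part of the pattern, since co-differing pairs had lengths within 10% of each other in 16.0% of cases against 13.1% of other pairs, a difference of 2.88 points with an interval of -2.26 to 8.42, and overlap of neighbouring gene models was not tested.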
